A study of Branchiostoma lanceolatum with 24 samples.

How the data were processed

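RNA was measured in whole embryos of the European amphioxus Branchiostoma lanceolatum, a cephalochordate, that had been kept in sea water with 0.1% DMSO or with 50 µM SU5402. SU5402 is a small molecule that blocks the tyrosine kinase of FGF receptors, and DMSO is its solvent. Per the labels' protocols, total RNA was extracted with a column kit, mRNA was taken from 2 µg of total RNA with oligo-dT beads, and libraries were made with random primers by a protocol that does not mark strand. The same protocols give 15 PCR cycles for the libraries of 6 h exposure and 12 cycles for those of 3 h and 9 h. Cycle number therefore goes with exposure time and is the same in the SU5402 and DMSO libraries of each comparison.

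The deposited table holds raw read counts, whole numbers at or above 0, for 96094 transcriptome contigs in 24 libraries. BWA 0.6.1 is named in the submitters' processing notes, and the assembly behind the contigs, the counting rule and any read filter are not given in the sources used here. All 24 columns bear the titles of the samples, and 0 columns were left unused. Each contig has an identifier made of a prefix and a number, and the table pairs none with a gene name. The RefSeq gene table given for the species, for assembly klBraLanc5.hap2, matched 0 of the contig identifiers. Gene names, positions and functions are therefore not reported here, and the gene lists fixed before the data were examined could not be tested. A contig is an assembled piece of transcript. Several contigs can come from 1 gene, near-identical gene copies can share reads, and overlapping genes on opposite strands cannot be told apart, so counts of contigs are not counts of genes.

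The counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Contigs with too few reads for a group of 2 were left out with filterByExpr, which kept 87512 contigs holding at least 99.88% of the reads of each library and left out 8582. Library sizes were scaled with trimmed mean of M-values (TMM) factors. A quasi-likelihood negative binomial model with 1 coefficient for each of the 12 groups was fitted to all 24 libraries, with 12 residual degrees of freedom. Contrasts were tested two-sided with glmQLFTest, and p-values were adjusted by the Benjamini-Hochberg method within each contrast at a threshold of 0.05. Adjusted p-values are from this fit unless another is named. Contigs past the threshold are said to have risen or fallen. Levels are CPM computed from the deposited counts with library sizes and TMM factors, given as mean ± SD of 2 libraries. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic, not a separate estimate. It can be too small where a group holds few reads. ContigAmph54642, with 0 to 10 reads in each DMSO library, is such a case, and its SE understates counting error. ContigAmph11822 at early 9 h, with 17 and 13 reads in its SU5402 libraries, is another, and further named contigs with few reads in a group may be too.

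Tested contrasts were SU5402 against DMSO at each of 6 combinations of stage and exposure time, the difference of that effect between stages at each exposure time, its difference between 9 h and 3 h in each stage, and the change from 3 h to 9 h in DMSO embryos. Without gene names, the rule fixed before the data were examined names, for each SU5402 comparison, the 2 contigs that rose and the 2 that fell with the smallest p. The replicate number in the labels was not used as a block, since the labels do not say what it marks. Nothing in the labels says that the 2 libraries of a group came from separate spawnings or dishes, so p-values measure the spread between these libraries, which may be technical. The counts of every replicate pair differed by more than sampling noise, with a chi-square of 1.39 per degree of freedom in the closest pair, DMSO late 6 h, and all 24 libraries were counted separately.

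Spread between replicates differed by stage. The biological coefficient of variation of a pair was 23.7% to 30.4% in the early groups and 3.42% to 7.62% in the late groups, while the single fit used a common value of 18.3%. A fit of the 12 libraries of each stage, planned as an alternative, gave 27.2% for the early and 6.83% for the late series, with 6 residual degrees of freedom. Its counts stand beside those of the single fit in the report. On simulated counts with the spread of each stage and 200 changed contigs in the 6 h comparison of each series, the single fit over 79126 contigs recovered 8.96%, 25.4% and 77.3% of changes of 1.5-fold, 2-fold and 4-fold in the early comparison. There, 46% of its 137 calls were false. In the late comparison it recovered 0%, 11.9% and 78.8%, with 0% of 60 calls false. The fit of the 12 early libraries, over 68379 contigs, recovered 0%, 4.48% and 37.9%, with 20% of 35 calls false. The fit of the 12 late libraries, over 69661 contigs, recovered 35.8%, 62.7% and 93.9%, with 5.88% of 136 calls false. The simulated libraries were drawn independently of each other and few contigs changed, so these shares need not hold for the real counts, whose early replicate differences are partly shared between groups.

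Developmental position was computed from log2 CPM with a prior count of 2. The axis ran from the 3 h to the 9 h DMSO library of 1 replicate number, over contigs that changed more than 4-fold and reached 5 CPM. Libraries other than those 2 were projected on it, on a scale from the earlier to the later collection time in hours post fertilisation (hpf), and the results of the 2 axes were averaged. The number of contigs expected with a read at a common depth of 10000000 reads was computed from the hypergeometric distribution. As a count without a model, contigs of at least 5 CPM in the higher group were counted where each SU5402 library was at least 2-fold above, or 2-fold below, each DMSO library. The same count was made for the other 2 splits of the 4 libraries. Contigs outside the range of the DMSO early 3 h and 9 h libraries were those with both libraries of a group at least 2-fold above or below all 4 of these, at 5 CPM or more on the higher side. Classes of level were set by the mean CPM over all 24 libraries. Classes by the DMSO level alone, used first, were replaced because a low DMSO level favours a rise by construction.

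Alternatives fixed before the data were examined were DESeq2 size factors, no filter on low counts, a filter of 1 CPM in 4 libraries, the Wald test of DESeq2 1.42.0, the replicate block, a further threshold of an absolute log2 fold change above 1, fits of the libraries of the stage or of the 4 libraries compared, and leaving out each library. Added after seeing the data were library totals without scaling factors, TMM factors from contigs of at least 10 CPM on average, limma-voom with a variance weight per stage, a replicate block with crossed numbers in 1 pair, the stage fit for the differences between times, the count without a model, classes of level by the mean over all 24 libraries and 2 other settings of the developmental position.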

Results

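Gene expression was measured by RNA-seq in whole amphioxus embryos to compare control embryos with embryos exposed to SU5402, an inhibitor of FGF receptor signalling, at 2 stages and 3 exposure times. In the early series, treatment began at 5 hpf and embryos were collected at 8, 11 and 14 hpf, after 3, 6 and 9 h. In the late series, treatment began at 15.5 hpf and embryos were collected at 18.5, 21.5 and 24.5 hpf. Each of the 12 groups held 2 libraries. Library totals ran from 10866511 reads, in DMSO late 6 h replicate 2, to 39988564 reads, in SU5402 early 3 h replicate 1. The 8 libraries of 6 h exposure held 10866511 to 18924324 reads, and the other 16 held 27687922 to 39988564. A single contig, ContigAmph3515, singled out after its values were seen, took 3.9% to 13.6% of the reads of a library. The first principal component of log2 CPM, which separated the early from the late libraries, held 58.2% of the variance.

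After 3 h of early treatment, ContigAmph24501 and ContigAmph4815 rose and ContigAmph23744 and ContigAmph4311 fell with the smallest p. ContigAmph24501 rose from 2.54 ± 0.185 CPM in DMSO to 69 ± 0.331 CPM in SU5402 embryos (SD, n = 2), a log2 fold change of 4.76 (SE 0.17, adjusted p = 6.8e-12). ContigAmph4815 rose from 0.824 ± 0.0922 to 22.5 ± 0.216 CPM (log2 fold change 4.77, SE 0.18, adjusted p = 1.1e-11). ContigAmph23744 fell from 111 ± 14.9 to 21.6 ± 0.684 CPM (log2 fold change -2.36, SE 0.11, adjusted p = 1.4e-10), and ContigAmph4311 from 91.3 ± 1.25 to 28.8 ± 0.475 CPM (log2 fold change -1.67, SE 0.086, adjusted p = 6.2e-10). In all, 9873 contigs rose and 10467 fell, of which 8191 and 3528 changed more than 2-fold. The mean level over all 24 libraries had a median of 0.849 CPM for the risen and 8.91 CPM for the fallen contigs. The fit of the 12 early libraries called 6441 risen and 6735 fallen, and 13061 contigs were called in the same direction by both fits. Its adjusted p-values were larger, at 1.4e-06 for ContigAmph24501, 1.8e-05 for ContigAmph4815, 2.8e-05 for ContigAmph23744 and 2.7e-05 for ContigAmph4311. DESeq2 size factors turned the split, to 11226 risen and 8456 fallen, as did library totals, with 11393 and 8276, and the Wald test of DESeq2, with 8089 and 7413. With TMM factors from abundant contigs it was 16436 and 4569. The fit of the 4 libraries compared gave 4356 and 2266, and limma-voom with a variance weight per stage 7962 and 7921. Without a filter, with the stricter filter and with the replicate block, plain or crossed, more contigs fell than rose.

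After 6 h of early treatment, ContigAmph24501 stood at 187 ± 6.41 CPM in SU5402 against 1.54 ± 0.472 CPM in DMSO embryos (SD, n = 2; log2 fold change 6.95, SE 0.19, adjusted p = 8e-14). ContigAmph54642 rose from 0.166 ± 0.022 to 16.8 ± 0.0264 CPM (log2 fold change 6.61, SE 0.23, adjusted p = 3.4e-12). ContigAmph26396 fell from 52.7 ± 6.81 to 4.59 ± 0.768 CPM (log2 fold change -3.53, SE 0.18, adjusted p = 1.7e-10), and ContigAmph23744 from 100 ± 12.5 to 17.8 ± 0.822 CPM (log2 fold change -2.49, SE 0.11, adjusted p = 5.2e-11). The comparison gave 12837 risen and 11641 fallen contigs, and 11381 and 5079 of these changed more than 2-fold. Of the contigs risen at 3 h, 68.6% were also risen at 6 h, and of the fallen 56.4% were also fallen. With the 12 early libraries alone, adjusted p-values were 9.9e-08 for ContigAmph24501, 4.9e-07 for ContigAmph54642, 2.3e-05 for ContigAmph26396 and 1.1e-05 for ContigAmph23744. In that fit 10700 contigs rose and 6890 fell. Leaving out DMSO early 6 h replicate 2 turned the split, to 8420 risen and 8790 fallen. Scaling moved it, to 15540 risen and 7790 fallen with library totals and to 18539 and 5478 with TMM factors from abundant contigs.

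After 9 h of early treatment, ContigAmph24501 reached 560 ± 9.18 CPM against 1.64 ± 0.12 CPM in DMSO embryos (SD, n = 2; log2 fold change 8.41, SE 0.19, adjusted p = 1.3e-15). ContigAmph54642 reached 75.7 ± 2 CPM against 0.185 ± 0.0319 CPM (log2 fold change 8.64, SE 0.2, adjusted p = 1.3e-15). Both contigs that fell with the smallest p were ones that had increased in controls between 11 and 14 hpf. ContigAmph14018 went from 31 ± 5.63 to 183 ± 14.7 CPM in DMSO embryos over that time and stood at 20 ± 0.713 CPM in SU5402 embryos at 14 hpf (log2 fold change -3.20, SE 0.1, adjusted p = 2.6e-13). ContigAmph11822 stood at 10.9 ± 0.0617 CPM in DMSO and 0.479 ± 0.0432 CPM in SU5402 embryos at 14 hpf (log2 fold change -4.48, SE 0.16, adjusted p = 1.7e-12). In all, 14250 contigs rose and 9509 fell. The 12 early libraries fitted alone gave 10081 risen and 5596 fallen, and TMM factors from abundant contigs gave 17482 and 6346. Adjusted p-values in the fit of the 12 early libraries were 1.7e-08 for ContigAmph24501 and ContigAmph54642, 2.6e-06 for ContigAmph14018 and 1.3e-05 for ContigAmph11822.

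Late treatment raised ContigAmph24501 within 3 h, from 1.33 ± 0.497 to 520 ± 11 CPM (SD, n = 2; log2 fold change 8.63, SE 0.19, adjusted p = 1.2e-15). ContigAmph54642 rose from 0.127 ± 0.0394 to 63.6 ± 1.36 CPM (log2 fold change 8.88, SE 0.21, adjusted p = 1.2e-15). Its DMSO libraries held 3 and 6 reads, so this SE is too small. ContigAmph13823, an abundant contig, fell from 1220 ± 12.5 to 376 ± 15.2 CPM (log2 fold change -1.70, SE 0.082, adjusted p = 1e-10), and ContigAmph19729 from 47 ± 1.31 to 10.4 ± 1.13 CPM (log2 fold change -2.18, SE 0.11, adjusted p = 1.7e-10). The single fit called 7509 risen and 4179 fallen contigs. The fit of the 12 late libraries, in which replicates lay closer together, called 11995 risen and 10201 fallen, and 10924 contigs were called in the same direction by both. Over all 24 libraries the mean level had a median of 1.17 CPM for the risen and 7.82 CPM for the fallen contigs.

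After 6 h of late treatment, ContigAmph24501 stood at 466 ± 26.7 CPM against 1.26 ± 0.246 CPM in DMSO embryos (SD, n = 2; log2 fold change 8.50, SE 0.2, adjusted p = 4.2e-15). ContigAmph54642 had 1459 reads in the SU5402 pair and 1 read in the DMSO pair, a ratio of 1380 with an exact 95% interval of 247 to 54500 that covers counting error only (adjusted p = 2.1e-14 in the edgeR fit). ContigAmph7823 fell from 341 ± 22.3 to 56.5 ± 3.32 CPM (log2 fold change -2.59, SE 0.1, adjusted p = 1.5e-11), and ContigAmph303 from 324 ± 24 to 64.6 ± 4.53 CPM (log2 fold change -2.33, SE 0.12, adjusted p = 8.4e-10). The single fit called 3847 risen and 3367 fallen contigs, and the fit of the 12 late libraries 8005 and 7772. Which direction held more contigs depended on scaling. DESeq2 size factors gave 3509 risen and 3969 fallen and its Wald test 2929 and 4008, while library totals gave 4676 and 2828. Both contigs that fell with the smallest p were also lower with SU5402 in the 3 early comparisons, ContigAmph7823 by log2 fold changes of -1.24, -1.60 and -1.32 and ContigAmph303 by -0.66, -0.79 and -0.58, all past the threshold.

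At 9 h of late treatment, ContigAmph24501 was at 427 ± 49.9 CPM against 1.86 ± 0.156 CPM (SD, n = 2; log2 fold change 7.84, SE 0.19, adjusted p = 4.2e-15) and ContigAmph54642 at 51 ± 4.67 against 0.243 ± 0.0682 CPM (log2 fold change 7.69, SE 0.19, adjusted p = 4.9e-15). ContigAmph532 fell from 209 ± 5.92 to 32.1 ± 2.46 CPM (log2 fold change -2.70, SE 0.13, adjusted p = 3.4e-10). ContigAmph16200 fell from 50.2 ± 1.36 to 4.03 ± 0.853 CPM (log2 fold change -3.63, SE 0.21, adjusted p = 3.4e-09). The same contig had risen at 3 h, from 11.1 ± 0.757 to 52 ± 0.126 CPM (log2 fold change 2.23, adjusted p = 1.6e-07). The single fit called 3216 risen and 2628 fallen contigs, and the fit of the 12 late libraries 8543 and 8194. The Wald test of DESeq2 gave 2747 risen and 2928 fallen, DESeq2 size factors 2977 and 2854, and library totals 3783 and 2372.

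**Figure D1:**
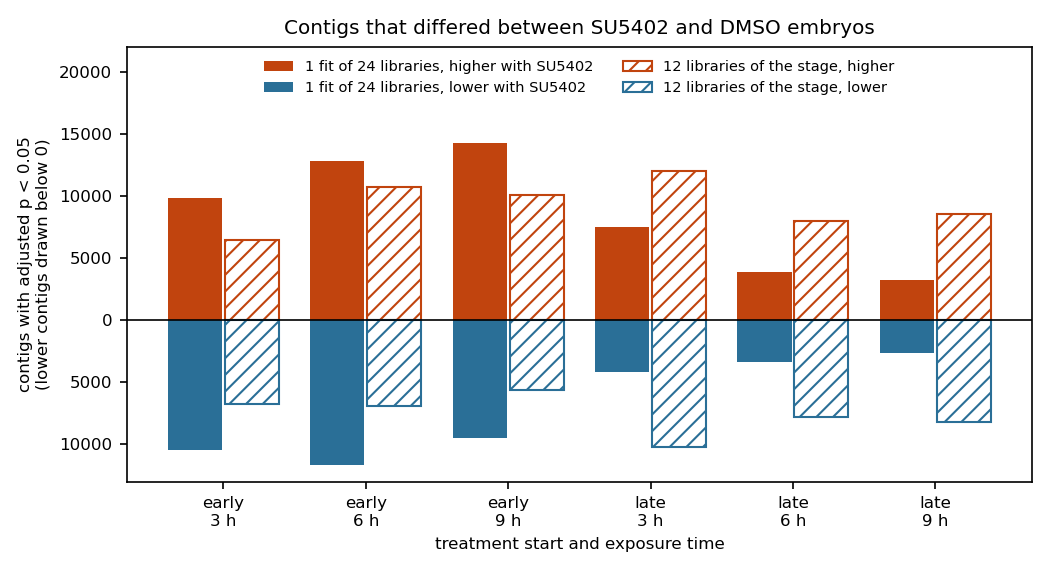
Number of contigs higher (above 0) or lower (below 0) with SU5402 at an adjusted p under 0.05, for each treatment start and exposure time; filled bars are the single fit of 24 libraries and hatched bars the fits of the 12 libraries of each stage. The single fit gives 20340 to 24478 calls in the early and 5844 to 11688 in the late comparisons, while the stage fits give 13176 to 17590 and 15777 to 22196.

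The order of the 2 series by number of calls differed between these fits at 3 and 9 h. Replicates were farther apart in the early series, and neither kind of fit models the replicate differences that its groups share. Without a model, 779, 1180 and 1211 contigs were at least 2-fold higher in each early SU5402 library than in each DMSO library at 3, 6 and 9 h, and 515, 1042 and 601 were at least 2-fold lower. The other 2 splits of the same libraries gave 512 and 0 contigs at 3 h, 356 and 0 at 6 h, and 0 and 255 at 9 h, both directions together. In the late series, 831, 458 and 334 contigs were higher and 376, 531 and 387 lower by this count, against 0 and 0, 0 and 7, and 0 and 0 for the other splits. Of the contigs at 5 CPM or more, these were 6.28%, 11% and 8.87% in the early and 5.88%, 4.98% and 3.48% in the late series. With 2 libraries in each group, chance alone parts the groups without overlap at 33.3% of contigs, before the 2-fold limit is set. By this count the series were close at 3 h, and the early one had more such contigs at 6 and 9 h. The count also ignores the replicate differences shared between early groups, which can lower the early counts. The closeness at 3 h may come from this. These counts were not themselves tested.

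The share of contigs that rose or fell varied with their mean level over all 24 libraries. At 6 h of early treatment, 17.4% of the contigs under 1 CPM rose and 1.96% fell, while 9.02% of those over 10 CPM rose and 44.9% fell. In the late 6 h comparison, 3.02% of the rare contigs rose and 0.783% fell, and 7.14% of the abundant ones rose and 13.5% fell. Few reads limit the calls among rare contigs, and these shares were not tested against each other. The median log2 fold change was 0.18, 0.13 and 0.07 for the rare and -0.08, -0.06 and 0.00 for the abundant contigs at 3, 6 and 9 h of late treatment. The size of the fall of abundant contigs in the early series depended on the scale. With library totals, 14.3% of them rose and 32% fell at 6 h of early treatment, and the median log2 fold change of all contigs moved to 0.11 at 3 h and 0.17 at 6 h. With TMM factors from abundant contigs, that median moved to 0.33, 0.32 and 0.19 at 3, 6 and 9 h. These factors centre the abundant contigs, so their even split on this scale, 20.4% risen and 22.6% fallen at 6 h, is built in and cannot show which scale holds.

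**Figure D2:**
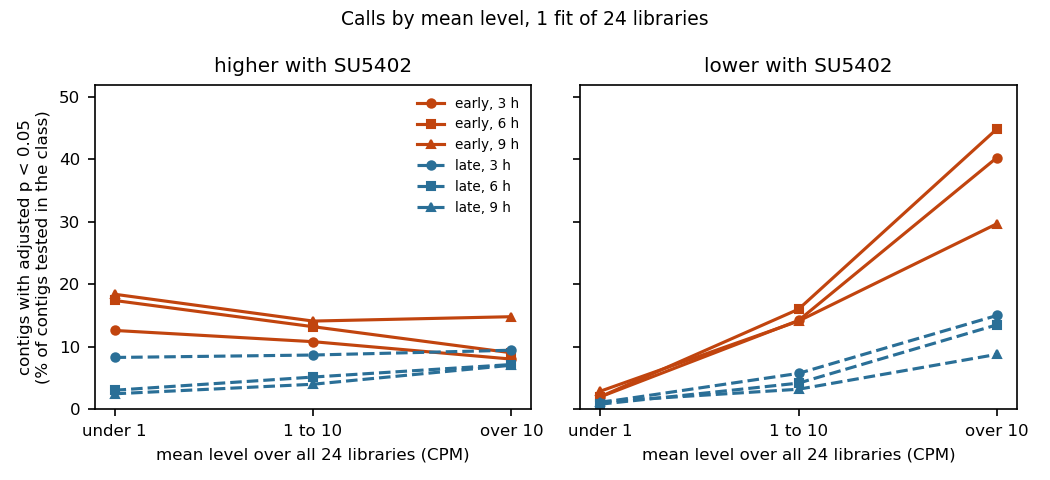
Share of tested contigs that rose (left) or fell (right) with SU5402 in 3 classes of mean level over all 24 libraries in CPM, for the early (solid) and late (dashed) comparisons at 3 h (circles), 6 h (squares) and 9 h (triangles), from the single fit of 24 libraries. On the TMM scale the risen share is highest for rare contigs in the early series, up to 18.4%, and for abundant contigs in the late series, up to 9.43%; the fallen share is highest for abundant contigs, up to 44.9%.

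The effect of SU5402 differed between late and early treatment at 8639 contigs after 3 h, 8915 after 6 h and 9944 after 9 h. The difference, late minus early, was above 0 for 5559, 5338 and 4850 of them and below 0 for 3080, 3577 and 5094. These splits moved with scaling, to 4197 above and 3805 below at 3 h and 3515 and 4197 at 6 h with DESeq2 size factors, and to 3811 and 4167 at 6 h with library totals. With TMM factors from abundant contigs they were 3109 and 5118, 2282 and 5533, and 2995 and 6730. The effect was larger in size in the early series at 67.2%, 79.7% and 80.6% of the contigs that differed. The single spread is too small for the early and too large for the late replicates. This can favour contigs with a large early effect from noise, so these shares may be too high. Effects past the threshold in opposite directions were found at 777, 599 and 589 of them. No number for independent lists was computed for these, so they do not show an excess of reversals. ContigAmph4815 rose with early treatment at 3 h and had a log2 fold change of -0.39 with late treatment at that time, with an adjusted p of 0.081 in the single fit and 0.0094 in the fit of the 12 late libraries, a difference of -5.15 (SE 0.23, adjusted p = 2.1e-10). ContigAmph24501 rose more with late than with early treatment at 3 h, by 3.87 on the log2 scale (SE 0.24, adjusted p = 1.1e-08), while at 9 h the difference was -0.57 (SE 0.24, adjusted p = 0.13). ContigAmph14018 fell more with early treatment at 9 h, the difference being 2.74 (SE 0.14, adjusted p = 1e-09). limma-voom with a variance weight per stage called 9866, 8768 and 13312 contigs, and at 6 h 4335 of these were above 0 and 4433 below. Leaving out SU5402 early 9 h replicate 1 turned the 9 h split, to 4295 above and 3373 below.

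Between 3 h and 9 h of early treatment the SU5402 effect changed at 10330 contigs, upward at 6490 and downward at 3840. Of these, 930 had fallen at 3 h and risen at 9 h, and 542 had risen at 3 h and fallen at 9 h. For such reversals, here and in the late series, no number for independent lists was computed. The effect on ContigAmph24501 grew by 3.65 on the log2 scale (SE 0.24, adjusted p = 2.2e-08), and that on ContigAmph4815 went from 4.77 to 0.55 (adjusted p at 9 h of 0.0078 in the single fit and 0.12 in the fit of the 12 early libraries), a change of -4.21 (SE 0.23, adjusted p = 2.9e-09). In the fit of the 12 early libraries there were 2900 upward and 1278 downward changes, and TMM factors from abundant contigs 4845 and 5070. During late treatment the effect changed at 3063 contigs, upward at 885 and downward at 2178, and 211 contigs had risen at 3 h and fallen at 9 h. ContigAmph16200 was one of these, with a change of -5.87 (SE 0.28, adjusted p = 1.8e-09). Fitted alone, the 12 late libraries gave 5084 upward and 6327 downward changes.

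A set of 506 contigs rose in all 6 comparisons and 185 fell in all 6. Independent lists of these sizes would share 0.0327 and 0.00835 contigs. No library served in more than 1 of these comparisons. All lists come from 1 fit with 1 spread per contig, and calls vary with level. Both can favour the same contigs in each list. The values for independent lists, here and for the control change below, can thus be too low and are not chance levels. The 506 risen contigs had a median DMSO level of 0.129 to 0.368 CPM, and their median log2 fold change was 2.55, 4.29 and 4.71 in the early and 3.92, 3.66 and 2.94 in the late series. The 185 fallen contigs had a median DMSO level of 33.8 to 70.4 CPM, and fell by medians between 0.69 and 1.05 on the log2 scale. In SU5402 embryos the medians were 1.53 to 5.42 CPM for the risen and 18.9 to 33.8 CPM for the fallen contigs. The gap in DMSO level is partly built into the direction of the calls, but the fallen contigs were the more abundant with and without SU5402. In the fits by stage, over 62963 contigs tested in both, 566 rose and 273 fell in all 6. With TMM factors from abundant contigs 651 rose and 73 fell. Within the early series 5169 contigs rose and 2357 fell at all 3 times, against 236 and 151 for independent lists. Within the late series 1562 rose and 777 fell, against 12.1 and 4.83. At 9 h, 1649 contigs rose in both series where independent lists would share 524, and 828 fell in both against 286. Of the 87512 contigs tested, 44422 changed in at least 1 of the 6 comparisons.

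**Figure D3:**
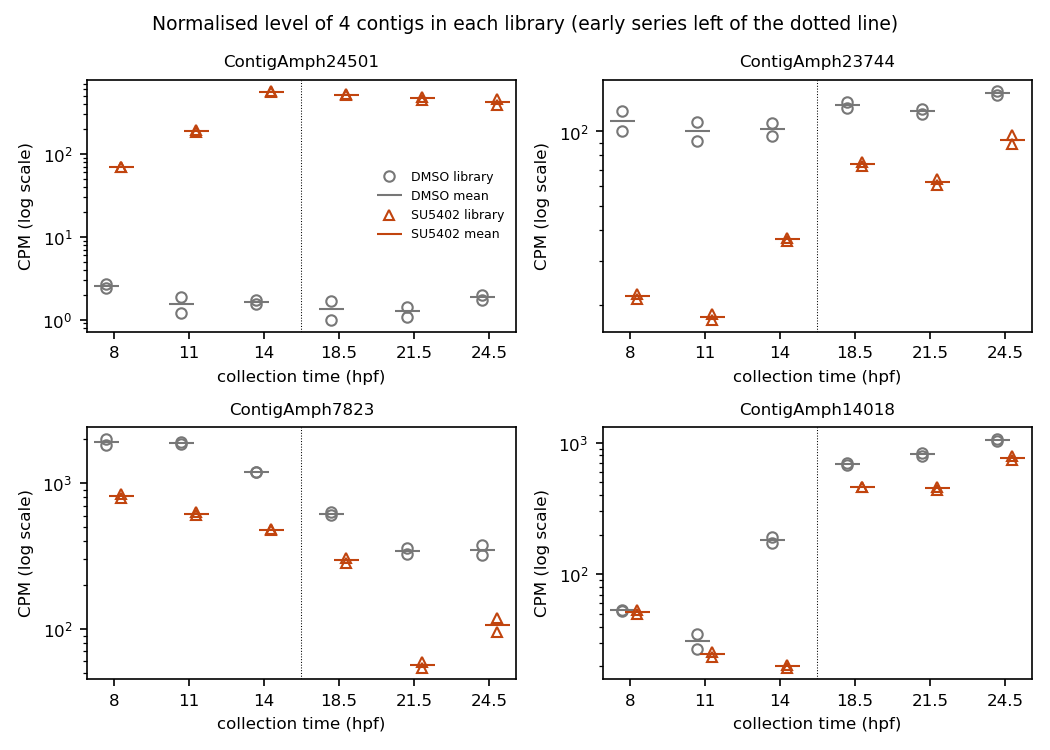
Normalised level in CPM (log axis) of 4 contigs in each DMSO (circles) and SU5402 (triangles) library by collection time in hpf, with bars at the mean of the 2 libraries. ContigAmph24501 stays at 1.26 to 2.54 CPM in DMSO means and reaches 69 to 560 CPM with SU5402; ContigAmph23744 and ContigAmph7823 are lower with SU5402 at each time, and ContigAmph14018 has its widest gap at 14 hpf.

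Control embryos changed over the same intervals. From 8 to 14 hpf, 18538 contigs rose and 20905 fell in DMSO embryos, and from 18.5 to 24.5 hpf 7137 rose and 4999 fell. The fits by stage called 15877 and 15658 in the early and 12774 and 11659 in the late series. Library totals gave 23491 risen and 16093 fallen in the early series, and TMM factors from abundant contigs gave 8999 and 3484 in the late series. The SU5402 effect at 6 h was set against this change, since the 2 contrasts share no library. Of the contigs that rose in early controls, 6792 fell with SU5402, where independent lists would share 2466, and 887 rose, against 2719. Of those that fell in early controls, 4264 rose with SU5402, against 3067, and 1733 fell, against 2781. The slope of the 6 h effect on the control change, across the contigs that changed in controls, was -0.245 in the early series, with a correlation across contigs of -0.456. Contigs are not independent replicates, and the values for independent lists have the limit given above. In the late series the slope was 0.0349. There, 699 of the contigs that rose in controls fell and 760 rose with SU5402, against 275 and 314 for independent lists, and 951 of those that fell in controls also fell with SU5402, against 192. With TMM factors from abundant contigs, 3866 of the early contigs that rose in controls fell with SU5402 and the slope was -0.251.

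Placed on the course of DMSO embryos, early SU5402 libraries stood at 8.08 ± 0.034 hpf at 8 hpf, against 8.15 ± 0.03 for DMSO libraries (SD, n = 2). At 11 hpf they stood at 10.4 ± 0.048 against 11.7 ± 0.0013, and at 14 hpf at 12.9 ± 0.15 against 13.9 ± 0.14. SU5402 minus DMSO on this axis was thus -0.0695 at 8 hpf, -1.34 at 11 hpf and -1.02 at 14 hpf, each more than the SD of either pair. DMSO libraries of 11 hpf stood at 11.7 and those of 21.5 hpf at 22.1, so position does not run evenly with collection time. Both are 6 h libraries, with more PCR cycles and fewer reads than the 3 h and 9 h libraries that set the axis. An uneven pace of change and this difference between libraries cannot be told apart. Units of the axis are not hours of delay, and differences at separate times cannot be ranked as delays. On the late course, the difference in axis units was 1.29 at 18.5 hpf, with SU5402 libraries ahead, -0.504 at 21.5 hpf and -0.993 at 24.5 hpf. The early course rested on 5324 and 5059 contigs for its 2 axes and the late course on 609 and 651. No test was run on these positions.

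**Figure D4:**
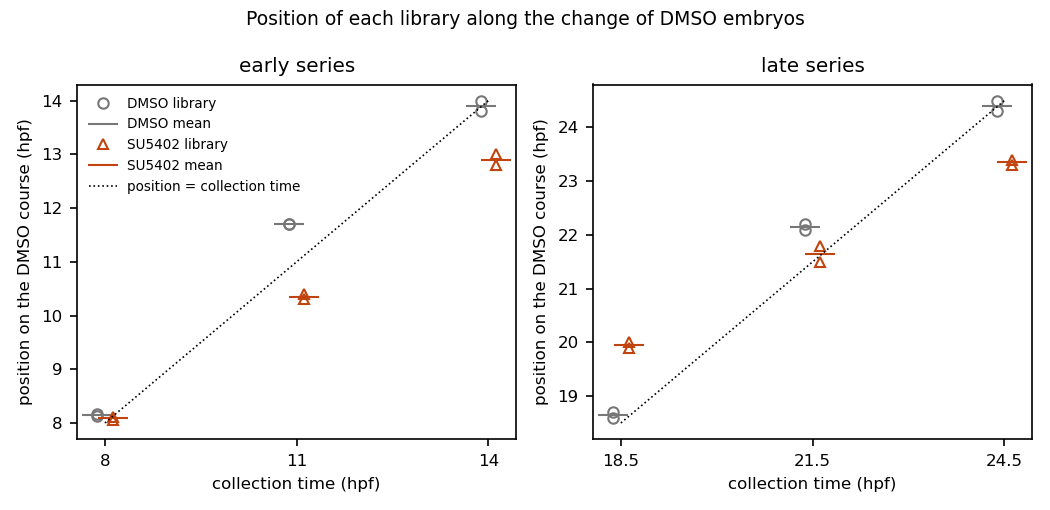
Position of each DMSO (circles) and SU5402 (triangles) library along the change of DMSO embryos, in hpf, by collection time, for the early (left) and late (right) series; bars are means of 2 libraries and the dotted line marks equal position and collection time. SU5402 means lie below DMSO means at 11 and 14 hpf and at 21.5 and 24.5 hpf, and above at 18.5 hpf.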

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

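The fits with a variance weight per stage and the stage fits of the time differences were chosen after the results were seen. The SU5402 effect differed between late and early treatment, by the test of the difference itself, at 8639 contigs at 3 h, 8915 at 6 h and 9944 at 9 h. It differed between 9 h and 3 h at 10330 contigs in the early and 3063 in the late series. Each of these tests shared 1 estimate of spread across 2 series whose replicates lay unequally far apart. limma-voom with a variance weight per stage gave 9866, 8768 and 13312 contigs for the differences between stages, and 7038 and 9702 for those between times. More time differences were thus called in the early than in the late series with 1 spread, and fewer with a spread per stage.

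Of the contigs named by the rule, several had effects that differed between stages at the hour at which they were named. All values are late minus early on the log2 scale. At 3 h the difference was 3.87 for ContigAmph24501, 4.31 for ContigAmph54642, 1.58 for ContigAmph23744 and 1.26 for ContigAmph4311. It was -5.15 for ContigAmph4815, -1.12 for ContigAmph13823 and -1.66 for ContigAmph19729. At 6 h it was 1.55 for ContigAmph24501, 3.61 for ContigAmph54642, 1.55 for ContigAmph23744 and 3.14 for ContigAmph26396, and -0.99 for ContigAmph7823 and -1.54 for ContigAmph303. The value for ContigAmph54642 at 6 h rests on 1 read in the late DMSO pair. With the variance weight per stage, limma-voom gave the 6 h difference of ContigAmph24501 an adjusted p of 0.078. At 9 h the difference was 2.74 for ContigAmph14018 and 4.27 for ContigAmph11822, and -1.17 for ContigAmph532 and -5.46 for ContigAmph16200. ContigAmph16200 fell with late treatment at 9 h and rose with early treatment at 9 h, by 1.82 on the log2 scale. Contigs named in 1 comparison were chosen there for a small p, so a smaller effect in the other series is partly built into the choice.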

How the results depend on the processing

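Alternatives that were not planned are those added after seeing the data, named as such in the methods. With DESeq2 size factors, no filter, the stricter filter, the Wald test of DESeq2, library totals, TMM factors from abundant contigs and the replicate block, all 13 counts stayed within 1.5 times. In the comparisons for which they were named, all 360 alternative values of the named contigs kept their direction and their side of the threshold. These contigs were named for the smallest p, so this result was likely from the choice alone. It does not extend to other calls or to other comparisons of these contigs. The gene list tests with their alternatives, and counts summed by gene name, were not run, since no contig has a name.

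The stage fits gave 13176 and 15677 contigs for early treatment at 3 h and 9 h, 22196, 15777 and 16737 for late treatment at 3, 6 and 9 h, 4178 and 11411 for the early and late time differences, and 24433 for the late DMSO change. Fits of the 4 libraries compared gave 6622, 10330 and 11946 in the early and 20596, 16552 and 14862 in the late series. limma-voom with a variance weight per stage gave 21867, 13224 and 14413 for late treatment, 9702 for the late time difference and 21838 for the late DMSO change. A log2 fold change above 1 left 11719 contigs for early 3 h, 7659, 4510 and 3621 for late treatment and 7133 for the late DMSO change; this threshold removes contigs by construction. The cause of these changes was not tested; the stage fits differ from the single fit in spread, residual degrees of freedom, contigs tested and scaling factors.

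Same-numbered replicates did not pair the samples throughout. The correlation across contigs of replicate differences between DMSO and SU5402 was 0.573, 0.438 and -0.509 at 3, 6 and 9 h in the early series and -0.0199, 0.00851 and -0.00757 in the late series. With the replicate block the counts in the 6 comparisons were 20660, 24201, 24249, 12012, 7413 and 6357, and the 9 h stage difference turned, to 5503 above 0 and 5196 below. Crossing the numbers of the SU5402 early 9 h pair in the block gave 30919, 31686 and 34650 contigs for early treatment, 21673, 13885 and 14940 for late treatment, 17270, 15141 and 19963 for the stage differences, 19479 and 10000 for the time differences and 22433 for the late DMSO change.

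Leaving out each library in turn leaves 1 library in a group, assumed to vary like the other groups. For early treatment this gave 13678 to 17383 contigs at 3 h, 16017 to 21233 at 6 h and 17252 to 19058 at 9 h, and SU5402 early 6 h replicate 1 alone moved a count, to 16017, by over 1.5 times. For late treatment it gave 6261 to 7400 at 3 h, 3124 to 4168 at 6 h and 2523 to 3284 at 9 h, and for the late DMSO change 6543 to 7430. Here each of the 4 libraries compared moved the count by over 1.5 times. The larger direction turned at early 3 h without SU5402 early 3 h replicate 2 (9061 risen, 8322 fallen) or 9 h replicate 1 (10797, 9363), and at late 6 h without DMSO replicate 2 (1768, 2030). For the early DMSO change it turned without SU5402 early 9 h replicate 1 (21204, 18363). The stage difference ran from 5393 to 7825 at 3 h, 5706 to 7906 at 6 h and 6122 to 8317 at 9 h. It moved by over 1.5 times at 3 h without DMSO late replicate 2 (5393) or SU5402 late replicate 1 (5716). At 6 h it did so without SU5402 early replicate 1 (5859), DMSO late replicate 2 (5706) or SU5402 late replicate 2 (5863). The 9 h split also turned without SU5402 early 3 h replicate 1 (5315 above, 5249 below) or 2 (5322, 5251). At 9 h the count moved by over 1.5 times without DMSO late replicate 1 (6448) or 2 (6122) or SU5402 late replicate 1 (6412). The early time difference ran from 7655 to 9213 and the early DMSO change from 32620 to 34833. The late time difference ran from 1446 to 2070, and each of its 8 libraries but SU5402 late 9 h replicate 2 moved it by over 1.5 times.

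The 185 contigs fallen in all 6 comparisons became 123 with library totals, 73 with TMM factors from abundant contigs and 605 with the crossed block. The early slope on the control change stayed between -0.26 and -0.237. Depth limits rare contigs most, and the 6 h libraries are the shallowest, with 10866511 to 18924324 reads.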

Other observations

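The tests on slower development, depth, scaling, crossed numbers, read sampling and a shared source were chosen after their results were seen. Those on timing between replicates, carry-over, SU5402 as the cause of a replicate difference and a foreign source were set before their values were seen. At a common depth of 10000000 reads, the number of contigs expected with at least 1 read was 76137 and 77384 in the DMSO early 3 h libraries and 81464 and 82460 in SU5402 early 3 h, and it was 84643 and 85989 in SU5402 early 6 h against 77175 and 78468 in DMSO. Both SU5402 libraries were above both DMSO libraries in 6 of the 6 comparisons. ContigAmph3515 took 8% and 7.95% of the reads in DMSO early 6 h and 13.6% and 11.9% in SU5402 early 6 h. Its share was also higher with SU5402 in the other comparisons except late 9 h. There it was lower, at 4.94% and 5.12% with SU5402 against 5.44% and 5.55% in DMSO.

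Early SU5402 embryos may have developed more slowly, a hypothesis drawn from the same data. Over contigs that change in DMSO embryos, the slope of the 6 h effect on the control change was -0.245. Slower development requires a negative slope, but a negative slope does not require slower development, so the sign alone cannot decide. Slower development as the whole early effect is argued against by contigs at least 2-fold outside the range of the DMSO early 3 h and 9 h libraries, 1251 in SU5402 early 6 h against 159 in DMSO early 6 h, a ratio of 7.87. Levels reached by controls only between the sampled times stay open for part of these.

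A set of 5963 contigs at or under 0.3 CPM in each DMSO group mean rose in at least 1 comparison. Together they took 0.0358% ± 0.001 of the reads in DMSO early 6 h and 0.605% ± 0.053 in SU5402 early 6 h (SD, n = 2). The gap was narrowest at late 9 h, with 0.033% ± 0.00027 in DMSO and 0.131% ± 0.012 in SU5402. The set was chosen for low DMSO levels and a rise, so such gaps are partly built in. Sequencing depth is argued against by the common-depth count, in 6 of 6 comparisons. Library scaling is argued against by a share of reads at least 3-fold higher with SU5402 in each comparison, taken without scaling on contigs chosen by the same rule from the 5 other comparisons, which share no library with it. One foreign source of fixed composition is argued against, within limits, by the log2 ratio of SU5402 early 6 h to late 3 h. Its SD over 192 contigs was 2.15 times that between replicates (95% bootstrap interval 1.83 to 2.58). The rule set beforehand asked for at least 2, and the interval reaches below that. Contigs entered the set through a rise in any comparison, including these 2, which can widen the ratio. The 2 SU5402 groups also differ in PCR cycles. A foreign source that changes with stage stays open, as does a response of the embryos to SU5402.

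Among the early libraries, the difference between replicates 1 and 2 had a shared profile, and the SU5402 early 9 h pair ran against it. Its correlation across contigs with the DMSO early 3 h difference was -0.456, while those of DMSO early 6 h and 9 h were 0.493 and 0.456. This is consistent with crossed replicate numbers in that pair, which would leave the unpaired comparisons as they are. Read sampling is argued against by a correlation of -0.598 at 8 CPM or more. Over contigs with no called change in controls from 3 h to 9 h, the correlation between DMSO early 3 h and 6 h was 0.519. Such contigs can still change below the threshold or between these times, and the DMSO early 3 h libraries served in choosing them. A difference in developmental timing alone thus stays open. Different parents of the 2 replicates were not tested and stay open.

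The 2 SU5402 late 6 h libraries differed more than 8-fold at 33 contigs with at least 50 reads, all higher in replicate 1, led by ContigAmph68708 at 18200 and 470 CPM, a contig singled out after its values were seen. For each member, the SD of the log2 ratio to ContigAmph68708 was taken over the other 22 libraries. Its median was 0.32 for the 2 other members with a median of at least 20 CPM. The log2 SD of ContigAmph68708 itself was 1.34, so these 3 may come from one source. For the 16 members from 1 to 20 CPM the median was 1.43, so as a group they kept no such ratio, though single members may have. Carry-over from DMSO early 9 h libraries is argued against by a median log2 ratio of -0.000305 over 154 contigs typical of them. The summed CPM of the set lay above both DMSO libraries in 1 and below both in 2 of the 6 comparisons. ContigAmph68708 makes up most of that sum. SU5402 treatment is thus argued against for this contig and stays open for the members under 20 CPM. What the source is stays open.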
